A study of Mus musculus with 7 samples.

How the data were processed

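Expression was measured on 7 Affymetrix Mouse Gene 1.0 ST arrays, 1 per sample, from total RNA labelled with biotin, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array, and the submitters' processing notes name Partek with no version, method or genome build. The summarisation, the background correction and the normalization are not given in the sources used here. That the scale is log2 was read from the values, which ran from 1.39 to 13.5 with array medians from 6.12 to 6.18. No array was centred again before testing. Between 6.86% and 13.1% of the genes tested had an identical value in a pair of arrays, at high levels too, which can make the spread of such genes in a group too small. The files used here give no detection calls, so signal over background was not known, and the number of arrays limits the precision.

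The platform annotation given for the probe sets named 1 gene symbol for 21789 of the 35557 probe sets, several for 1621 and none for 12147, and probe sets with several symbols were not named. Of the single-symbol probe sets, 21698 matched a gene table of the assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. That table was used for names and for which genes share a chromosome, and no coordinates are given because the arrays' build is not stated in the sources used here. Where several probe sets carried a symbol (999 genes), the probe set with the highest mean over all 7 arrays stood for the gene, which left 19938 genes. Samples were grouped by the PECAM status in the labels into 2 PECAM1− samples (parental cells and clone A1), 4 PECAM1+ clones (A2 to A5) and 1 MDEC sample.

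PECAM1+ and PECAM1− arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on the log2 values of the 6 B16F10 arrays, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. MDEC stayed out of that fit. The same fit without clone A1 or without parental cells gave the comparisons with parental cells and with clone A1. Differences are PECAM1+ minus PECAM1−, in log2 units. A total of 22 gene lists was fixed before the data were examined: endothelial identity without Pecam1, VEGF, FGF, angiopoietin and PDGF signalling, vasculogenic mimicry, melanocyte differentiation, neural crest-like melanoma, AP-2 and other transcription factors, epithelial-mesenchymal transition, basement membrane and matrix, integrins and adhesion, cell cycle, hypoxia and glycolysis, interferon response and antigen presentation, inflammatory cytokines and NF-kB, unfolded protein and amino acid stress, p53 targets, cholesterol synthesis, tumour-initiating cells, Notch signalling, and markers of leukocytes and platelets, fibroblasts and mural cells, keratinocytes and lymphatic endothelium. List members without a probe set of their own in the annotation, such as Cdkn1a, Isg15 and H2-K1, were not analysed here, and Car9 was entered in the hypoxia list under the symbol Ca9, which the annotation does not use. Lists were tested with limma camera (inter-gene correlation 0.01) and adjusted over the 22 lists, with an estimated correlation and fry beside it. A count "adjusted over the list alone" applies Benjamini-Hochberg to the members of that list.

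MDEC had 1 array, so a rule of size was used: at least 4-fold from the mean of the B16F10 group means and outside the range of the 6 B16F10 arrays. A list in a single array was described by the percentile of its median among 10000 random lists of the same size, matched on mean expression in 20 bins. Correlations with MDEC were compared by an exact permutation test over the 15 splits of 4 against 2 arrays. Genes were named by a rule fixed before the data were examined: Pecam1 and Tfap2a; the 12 largest positive and 12 largest negative differences among genes past the threshold with groups that do not overlap, filled up from genes with an unadjusted p under 0.01 that are said not to pass; up to 4 members of each list with the largest absolute difference; and for MDEC the 10 highest and 10 lowest genes and 8 lineage genes. Predicted genes, olfactory receptors and small RNAs were counted but not named by that rule. List members named for a single B16F10 sample or for MDEC, and genes named in the closing part, were chosen after their values were seen.

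Simulated arrays had independent noise with the same spread in every array, so none stood apart as clone A1 does in the data. Fits to a lone PECAM1− sample used the spread among the PECAM1+ clones. The recovery below therefore does not give the power in the data. With 200 planted genes among 19938, the fit against both PECAM1− samples recovered 65% of 2-fold and 88% of 4-fold changes with 7 false calls. The fit against parental cells alone recovered 59% and 84% with 6 false calls, and that against clone A1 alone 50% and 85% with 9. Camera called 20 of 20 planted lists of 20 genes and 1 of 20 unshifted ones. Genes of these lists were simulated as independent, so this does not check camera for lists whose members move together. The alternatives chosen before the data were examined were quantile normalization, median centring of each array, a filter at the 40th percentile of mean expression, every named probe set separately, all probe sets, eBayes without trend, robust eBayes, array weights, a threshold of 0.1, leaving out each B16F10 sample, an estimated correlation, fry, 2-fold and 8-fold rules, a limma fit with the B16F10 spread assumed for MDEC, Spearman's rho and a 1.5-fold rule. Figures were drawn with matplotlib 3.10.9.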

Results

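Gene expression was measured with single-colour Affymetrix Mouse Gene 1.0 ST arrays in 6 samples of B16F10, a pigmented mouse melanoma cell line, and in 1 sample of mouse dermal endothelial cells (MDEC). PECAM1 (CD31) is an adhesion receptor of endothelial cells, platelets and leukocytes. The labels gave PECAM status for every B16F10 sample. Parental B16F10 cells and clone A1 were PECAM1− (n = 2), and clones A2, A3, A4 and A5 were PECAM1+ (n = 4). The PECAM1− group joined a parental population with a clone, grouped by that label alone. The median log2 value of the arrays lay between 6.12 and 6.18. The labels did not say that samples of a group came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

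Pecam1 itself separated the groups on every array. Its log2 level was 5.27 in parental cells and 5.43 in clone A1, and 11.03 ± 0.03 (SD, n = 4) in the PECAM1+ clones. The MDEC array held 11.72. The PECAM1+ clones lay 5.68 ± 0.09 (SE) log2 units above the PECAM1− samples, with a limma adjusted p of 7.00e-05. Genes on the chromosome that carries Pecam1 had a median difference of −0.12 from parental cells and −0.07 from clone A1, far smaller than that of Pecam1 and in the other direction. Tfap2a, which encodes the transcription factor AP-2 alpha, was at 10.00 ± 0.07 (SD, n = 4) in the PECAM1+ clones and at 9.98 ± 0.13 (SD, n = 2) in the PECAM1− samples. Its difference of 0.03 ± 0.09 (SE) did not pass the limma test (adjusted p = 0.922), and its level in MDEC was 5.24.

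**Figure D1:**
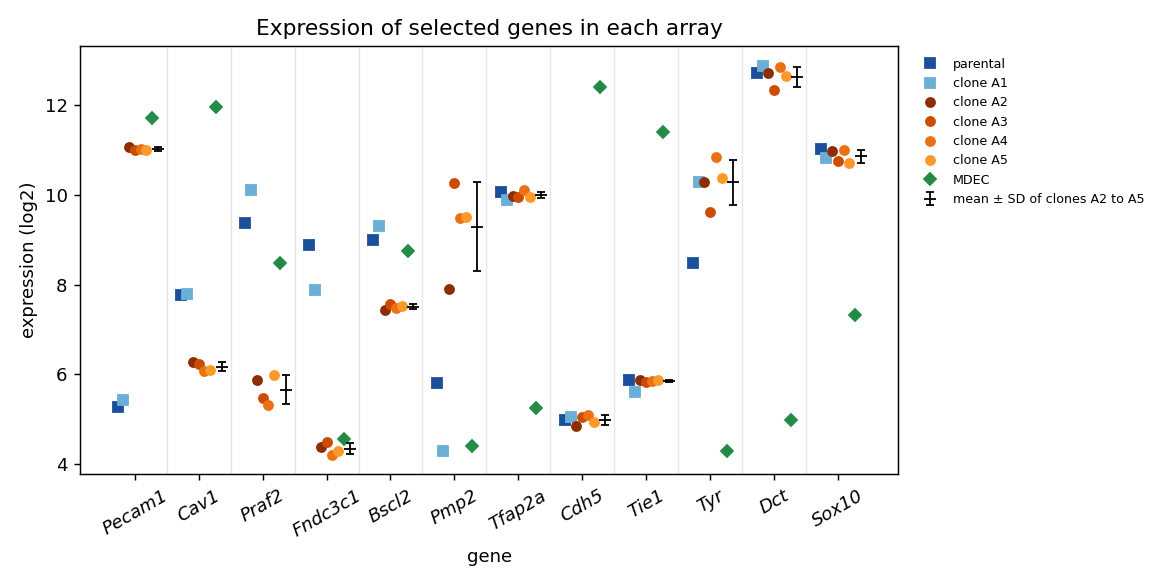
Expression of 12 genes in each of the 7 arrays (y axis, log2). Squares are the PECAM1− samples, circles the PECAM1+ clones, diamonds MDEC, and black bars the mean ± SD of clones A2 to A5. Pecam1 lay at 5.27 and 5.43 in the PECAM1− samples and near 11 in every PECAM1+ clone, while Cdh5 stayed near 5 in all B16F10 arrays and was 12.4 in MDEC.

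The comparison of PECAM1+ clones with the PECAM1− samples asked which genes differed between the groups. The sample titles did not say whether the 4 PECAM1+ clones arose independently. Differences they share therefore cannot be told apart from those of a common origin. Beside Pecam1, which rose, Cav1 fell in the PECAM1+ clones. Genes on its chromosome, that of Vwf, had a median difference of −0.07 from parental cells and −0.09 from clone A1. Cav1 encodes caveolin-1, a coat protein of caveolae. It was at 7.78 in parental cells, 7.80 in clone A1 and 6.17 ± 0.10 (SD, n = 4) in the PECAM1+ clones, a limma difference of −1.62 ± 0.08 (SE) with an adjusted p of 0.0167. These were the 2 genes called by limma among 19938 tested, 1 higher and 1 lower, where 1830 genes (9.18%) had an unadjusted p under 0.05. The groups did not overlap for 3272 genes (16.4%, where chance gives 13.3%), and 165 of these were also at least 2-fold apart, 100 higher and 65 lower in the PECAM1+ clones. Of those 165, 54 were at least 2-fold from each PECAM1− sample taken singly, since clone A1 differed from the mean of the clones by 2-fold for 1310 genes and parental cells for 131. The call of Cav1 was lost when clone A1 or any of the 4 PECAM1+ clones was left out (limma adjusted p from 0.0933 to 0.254) and with array weights (limma adjusted p = 0.205), and kept without parental cells. The difference itself stayed between −1.66 and −1.59 in all of these. Cav1 was also not called when all probe sets were tested, where Pecam1 was the 1 gene called. Between 1 and 6 genes were called under the other settings with all 6 arrays, and leaving out parental cells gave 4089.

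Several genes with large differences and separate groups did not pass the adjusted threshold. On the higher side, Pmp2 and Pmp22, which encode peripheral myelin proteins, differed by 4.24 ± 0.75 and 2.39 ± 0.37 (SE). Pmp2 was at 5.81 in parental cells, 4.29 in clone A1 and 9.30 ± 0.99 (SD, n = 4) in the PECAM1+ clones. Pkd1l1 differed by 2.27 ± 0.26, Apod by 2.25 ± 0.35, the lysozyme gene Lyz2 by 2.23 ± 0.53 and the succinate receptor gene Sucnr1 by 2.18 ± 0.54. The phosphatase gene Ptp4a3 differed by 2.12 ± 0.24, Plscr2 by 1.82 ± 0.34, the endothelin-converting enzyme gene Ece1 by 1.69 ± 0.23, the angiotensinogen gene Agt by 1.56 ± 0.29 and B3galt5 by 1.54 ± 0.39. On the lower side, Praf2 differed by −4.09 ± 0.29 and Fndc3c1 by −4.04 ± 0.28. Fndc3c1 was at 8.89 in parental cells, 7.88 in clone A1 and 4.34 ± 0.12 (SD, n = 4) in the PECAM1+ clones, and it passed against parental cells alone (limma adjusted p = 0.0254). Morc1 differed by −2.85 ± 0.43, the monoglyceride lipase gene Mgll by −2.70 ± 0.65, Npl by −2.60 ± 0.29, the carbonic anhydrase gene Car9 by −2.18 ± 0.32 and the plastin gene Pls3 by −2.15 ± 0.31. Capn6 differed by −1.90 ± 0.33, Sectm1a by −1.84 ± 0.30, Pacs1 by −1.84 ± 0.27 and the seipin gene Bscl2 by −1.65 ± 0.11. Bscl2 and Pacs1 lie on the chromosome of Vegfb, whose genes had a median difference of −0.21 from parental cells. Car9 lies on that of Tek (−0.14), Sectm1a on that of Pecam1 (−0.12) and Mgll on that of Vwf (−0.07). Praf2, Fndc3c1, Pls3 and Capn6 lie on that of Vegfd (0.02), Morc1 on that of Cldn5 (0.02) and Npl on that of Cd34 (0.05). The limma adjusted p of these 22 genes ran from 0.0585 to 0.428. Praf2 and Bscl2 passed with quantile normalization (limma adjusted p = 0.0273), median centring (0.0217), a filter on dim genes (0.0270) and robust eBayes (0.0394), and Fndc3c1 passed with all of these but the filter, which removed it before testing.

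Endothelial genes other than Pecam1 were not called between PECAM1+ clones and PECAM1− samples. Of 36 endothelial identity genes, 17 were higher and 0 passed in the PECAM1+ clones, over all genes or adjusted over the list alone. Against clone A1 alone, which is 1 array, 22 were higher and the median of the list was 0.02. Among those higher were Eng (0.68), Plvap (0.49), Lyve1 (0.33), Sox18 (0.30) and Tie1 (0.26). Lyve1 was low in B16F10, at 4.95 in clone A1 and a mean of 5.28 in the PECAM1+ clones, against 12.2 in MDEC. Clone A1 differed widely in general, with 1310 genes at least 2-fold from the mean of the PECAM1+ clones. Against parental cells alone, also 1 array, 14 were higher and the median was −0.03. Against both PECAM1− samples, the mean difference of the list was 0.03 and the median −0.01 (camera adjusted p = 0.498). The largest differences in that fit were 0.34 ± 0.19 (SE) for Eng, 0.30 ± 0.17 for Mmrn2, 0.26 ± 0.13 for Plvap and 0.20 ± 0.07 for Cldn5. Eng was well expressed in all B16F10 arrays (11.3 to 11.6 as group means) and at 11.7 in MDEC. The VE-cadherin gene Cdh5 was at 4.98 ± 0.10 (SD, n = 4) and 5.02 ± 0.05 (SD, n = 2), the VEGF receptor gene Kdr at 4.61 and 4.68, and the angiopoietin receptor gene Tek at 4.71 and 4.72 in PECAM1+ and PECAM1− samples.

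Of 22 gene lists, 4 rose in the PECAM1+ clones by limma camera. Cholesterol synthesis genes were higher in 17 of 18 members, with a mean difference of 0.37 (camera adjusted p = 9.00e-09, and adjusted p = 0.503 with an estimated correlation). No member passed over all genes, and 7 passed adjusted over the list alone. Hsd17b7 differed by 0.99 ± 0.19 (SE), Idi1 by 0.87 ± 0.21, Dhcr7 by 0.63 ± 0.24 and Cyp51 by 0.53 ± 0.10. Cholesterol synthesis was called by camera in every fit that left out 1 sample (adjusted p from 1.46e-08 to 4.20e-05), but with an estimated correlation not without clone A1 (adjusted p = 0.742) or without parental cells (0.588). Inflammatory cytokine and NF-kB genes were higher in 17 of 23 members, with a mean of 0.28 (camera adjusted p = 0.0243, and adjusted p = 0.564 with an estimated correlation). In that list 0 members passed over all genes and 3 adjusted over the list alone. Lif differed by 1.48 ± 0.22 and the chemokine receptor gene Ackr3 by 0.88 ± 0.15, while Cxcl10 was at 9.74 in parental cells, 11.36 in clone A1 and between 11.81 and 12.28 in the PECAM1+ clones (SD 0.21, n = 4). Targets of p53 were higher in 12 of 15 members, with a mean of 0.24 (camera adjusted p = 0.0214, and adjusted p = 0.503 with an estimated correlation). None passed over all genes or adjusted over the list alone, and Trp53inp1 differed by 0.82 ± 0.23, Plk2 by 0.58 ± 0.21 and Btg2 by 0.52 ± 0.21. The p53 call was lost without parental cells (mean 0.17, camera adjusted p = 0.408). The inflammatory call was lost without parental cells (mean 0.15, camera adjusted p = 0.242) or clone A3 (0.21, 0.0897), where the mean was lower, and also without clone A1 (0.40, 0.0577) and with the filter on dim genes (0.44, 0.0716), where it was higher.

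The cell cycle list rested on clone A1. All 24 measured members were higher in the PECAM1+ clones, with a mean difference of 1.51 (camera adjusted p = 5.10e-07, and adjusted p = 0.564 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Ccna2, which encodes cyclin A2, was at 11.5 in parental cells, 6.92 in clone A1 and 11.4 ± 0.07 (SD, n = 4) in the PECAM1+ clones. Plk1, Rrm2 and Bub1 were at 6.69, 7.75 and 6.09 in clone A1 and at 11.2, 11.7 and 9.98 in parental cells. Without clone A1 the mean turned to −0.08 (camera adjusted p = 0.553).

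The other lists were not called, with camera adjusted p from 0.101 to 0.665. Unfolded protein and amino acid stress genes had the largest mean difference of them, −0.34, and were called with quantile normalization (camera adjusted p = 0.0481), median centring (0.04998) and array weights (0.0391), but not with an estimated correlation (adjusted p = 0.564). That difference rested on clone A1, with a mean of −0.87 against clone A1 alone and 0.20 against parental cells alone. Mean differences were 0.18 for basement membrane and matrix genes, 0.15 for VEGF, FGF, angiopoietin and PDGF signalling, 0.15 for epithelial-mesenchymal transition, 0.11 for vasculogenic mimicry, 0.10 for integrins and adhesion, and 0.07 for Notch signalling. They were 0.02 for melanocyte differentiation, 0.02 for neural crest-like melanoma genes, 0.02 for tumour-initiating cell markers, −0.08 for hypoxia and glycolysis, and −0.11 for the interferon response. The list of AP-2 and other transcription factors had a mean of −0.02 and a median of 0.01. Markers of other cell types gave means of 0.10 for leukocytes and platelets, 0.13 for fibroblasts and mural cells, 0.05 for keratinocytes and 0.08 for lymphatic endothelium. Among members with larger differences, Thbs1 (thrombospondin-1) differed by 2.34 ± 0.95 (SE), Pgf (placental growth factor) by −1.05 ± 0.37, Fbln2 by −0.70 ± 0.08, Itga4 by 1.24 ± 0.43, Slpi by 1.20 ± 0.37 and Bnip3 by −0.83 ± 0.24, and none passed over all genes. Adjusted over the list alone, 1 VEGF signalling gene passed as higher and 1 matrix gene, Fbln2, as lower. With fry, which tests whether a list moves one way on balance, 0 of the 22 lists were called, and camera with estimated correlations also called 0. With mixed fry, which counts changes in either direction, 6 lists were called: p53 targets (adjusted p = 0.000193), inflammatory genes (0.00502), cholesterol synthesis (0.0147), matrix genes (0.0147), vasculogenic mimicry (0.0259) and VEGF signalling (0.0459).

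Parental cells and clone A1 differed from each other far more than parental cells differed from the PECAM1+ clones. Clone A1 had low cell cycle genes and high stress and interferon genes. The PECAM1+ clones had interferon genes higher than parental cells by a mean of 0.47. With an estimated correlation, camera called none of these lists in the fits against a single PECAM1− sample. Against clone A1 alone, limma called 4089 genes, 1861 higher and 2228 lower in the PECAM1+ clones, where the lone sample is assumed to vary like the others. All 24 cell cycle genes passed as higher than in clone A1 (median 3.19). In the unfolded protein and amino acid stress list, 11 of 18 genes passed as lower than in clone A1, among them Atf3 (−3.15), the cystine transporter gene Slc7a11 (−3.53), Trib3 (−2.29) and Dnajb9 (−2.16), and 3 passed as higher, the serine and glycine synthesis genes Psat1 (1.39), Phgdh (1.16) and Shmt2 (0.60). Camera gave that list an adjusted p of 0.00175, and adjusted p = 0.588 with an estimated correlation. The interferon list was lower than in clone A1 (12 of 24 genes passed as lower, such as Irf7 at −2.78 and Ifit3 at −1.55, and 1, Irf1, as higher; camera adjusted p = 5.27e-06, and adjusted p = 0.588 with an estimated correlation). In the same fit 8 of 18 cholesterol synthesis genes passed as higher.

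Against parental cells alone, limma called 2 genes, Pecam1 and Fndc3c1, and 2684 genes (13.5%) had an unadjusted p under 0.05. Here the interferon list rose, with 18 of 24 members higher and a mean of 0.47 (camera adjusted p = 2.20e-07, and adjusted p = 0.742 with an estimated correlation). No member passed over all genes and 11 passed adjusted over the list alone. Usp18, Ifit1 and Rsad2, all induced by interferon, differed by 1.58, 1.54 and 1.51 from parental cells, and Ccl5 of the inflammatory list by 2.60. Cholesterol synthesis (mean 0.27, camera adjusted p = 1.62e-05) and p53 targets (mean 0.31, camera adjusted p = 0.00112) were also higher than in parental cells, each with adjusted p = 0.742 with an estimated correlation.

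**Figure D2:**
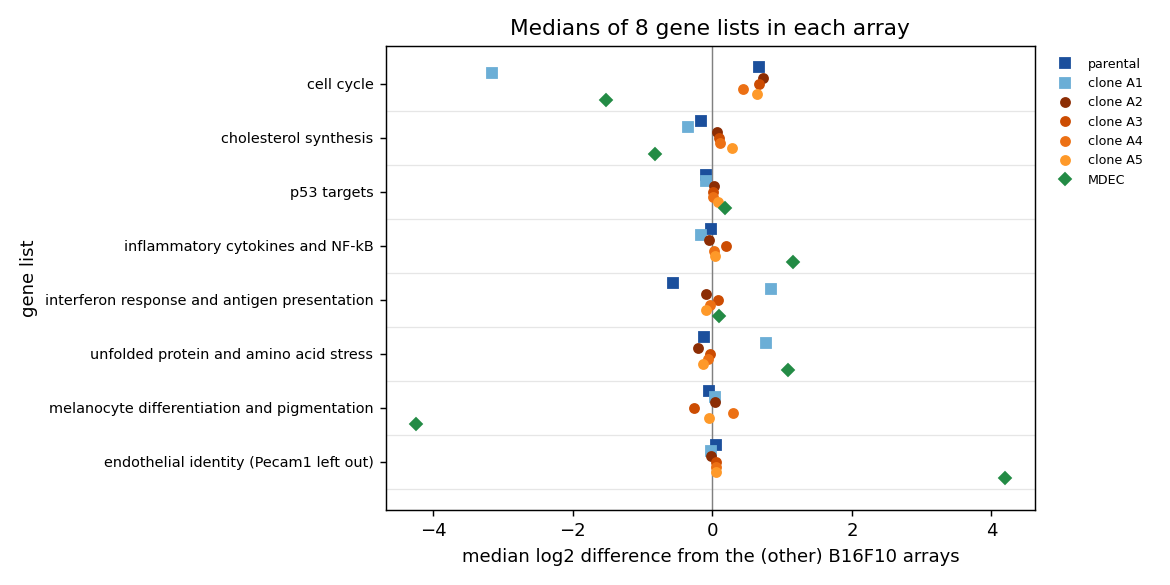
Median log2 difference of the genes of 8 lists (y axis) in each array from the mean of the other 5 B16F10 arrays, or for MDEC from the mean of the B16F10 group means (x axis). Squares are the PECAM1− samples, circles the PECAM1+ clones and diamonds MDEC. Clone A1 lay at −3.15 for the cell cycle list and at 0.84 for the interferon list, parental cells at −0.57 for the interferon list, and MDEC at 4.20 for the endothelial list and −4.25 for the melanocyte list.

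The spread between arrays showed the same order. Across genes, which are not independent replicates, the PECAM1+ clones correlated with each other at r from 0.994 to 0.997, with 30 to 159 genes at least 2-fold apart in a pair. Parental cells correlated with them at 0.990 to 0.995 (108 to 245 genes), and clone A1 correlated with the other B16F10 arrays at 0.967 to 0.970 (1325 to 1447 genes). The number of genes at least 2-fold away from the mean of the other 5 B16F10 arrays was 144 for parental cells, 1271 for clone A1, 31 for A2, 108 for A3, 78 for A4 and 41 for A5.

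MDEC were compared with B16F10 to place the clones between melanoma and endothelial cells. MDEC had higher endothelial genes and lower melanocyte genes than B16F10. Of the genes tested, 943 were at least 4-fold apart from the mean of the B16F10 group means and outside the range of all 6 B16F10 arrays, 543 higher and 400 lower in MDEC. There was 1 MDEC array, so this rule of size was used in place of a test. MDEC lay outside the B16F10 range for 52.9% of genes, where chance gives 28.6%. The highest were Ctla2a, Cdh5 (12.4), Cd24a, Cd34 (12.1), Emcn, Lyve1 (12.2), Cd93, Bmp4 (12.3), Tc2n and Cd53, and Kdr, Tek and Tie1 were at 9.15, 8.37 and 11.4. The lowest were Kcnma1, Tyrp1, Dct, Pmel, Xlr, Slc45a2, Scrn1, Bmpr1a, Neto2 and Emb. The melanin enzyme genes Tyrp1 and Dct were 8.03 and 7.73 log2 units below B16F10, and Mlana, Tyr and Sox10 were at 6.43, 4.29 and 7.33 against group means of 12.2 to 12.3, 9.39 to 10.3 and 10.9 in B16F10.

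The endothelial list had a median of 4.20 in MDEC, above the highest of 10000 random lists matched on mean expression (0.21), with 34 of 36 members higher. The melanocyte list had a median of −4.25, below the lowest random list (−0.76), though the receptor genes Kit and Ednrb were 4.89 and 4.52 higher in MDEC. Lymphatic endothelial markers (median 2.40), inflammatory genes (1.16), stress genes (1.08), Notch signalling (0.80) and the transcription factor list (0.76) were also above all random lists. Cell cycle genes were below them, with a median of −1.52 from a B16F10 mean that includes the low values of clone A1, and for Ccna2, Plk1 and Bub1 MDEC (8.84, 7.51 and 7.20) lay above clone A1, inside the B16F10 range. In the inflammatory list Ccl2 and Ptgs2 were 6.49 and 6.16 higher in MDEC and Cxcl10 was 5.68 lower.

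PECAM1+ clones were on average no closer to MDEC than PECAM1− samples were. Across genes, the correlation with MDEC was 0.906 ± 0.0026 (SD, n = 4) for PECAM1+ clones and 0.906 ± 0.00044 (SD, n = 2) for PECAM1− samples, a difference of −0.00029 (two-sided exact permutation p = 0.933, where 0.133 is the smallest that 4 against 2 arrays can give). The 542 genes at least 4-fold higher in MDEC, with Pecam1 left out, differed between the groups by a mean of 0.03 (camera adjusted p = 0.476). One of them passed the limma test, Cav1, which was at 11.97 in MDEC and fell in the PECAM1+ clones. The 400 genes at least 4-fold lower in MDEC differed by 0.13 (camera adjusted p = 0.0502, and adjusted p = 0.326 with an estimated correlation). That set passed when genes at least 8-fold apart were used (camera adjusted p = 0.00323), and when clone A1, A3 or A5 was left out.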

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

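The rule for an outlying array was fixed before the data were examined, and no test here was chosen after the results were seen. In 155 groups of 4 PECAM1+ clones tested, 11 had a clone far from the other 3, and chance flags about 1 in 20 groups (5 percent). Single genes far from the other clones were the following. In clone A4, Tfap2a was at 10.12 (others 9.96 to 9.97) and Rbpj, a Notch pathway factor, at 9.05 (others 9.37 to 9.40). In clone A2, Ptp4a3 was at 9.89 (others 9.64), the epithelial adhesion gene Epcam at 5.03 (others 5.56 to 5.61) and Cd53 at 3.93 (others 4.21 to 4.23). In clone A3, Plk2 was at 7.86 (others 7.21 to 7.28) and the aldehyde dehydrogenase gene Aldh1a1 at 7.14 (others 5.60). In clone A5, Icam1 was at 7.30 (others 7.14) and Tagln at 5.28 (others 5.47). The other clones had identical values for Tagln and for Aldh1a1, so any distance counted there. Some of the other clones were also tied for Tfap2a (A3 and A5) and for Ptp4a3, Icam1, Epcam and Cd53 (A3 and A4). Such ties make a flag easier to reach, and the chance rate of 5 percent does not allow for them. Of the gene lists, cholesterol synthesis had a mean of 0.20 in clone A5 (others 0.09 to 0.11) and tumour-initiating cell markers a mean of 0.19 in clone A3 (others −0.07 to −0.03).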

How the results depend on the processing

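All alternatives were chosen before the data were examined. Pecam1 kept its direction and its limma call throughout (5.60 to 5.76 when samples were left out). The endothelial list was called by camera under none of them, with means of 0.00 to 0.06 when samples were left out. Against 2 genes called, quantile normalization, median centring and an adjusted p under 0.1 gave 6 each, the filter on dim genes and robust eBayes 5 each, all probe sets and array weights 1 each, and leaving out samples 1 to 4089, the highest without parental cells. Against 4 lists called, an estimated correlation and fry gave 0 each. The genes lower in MDEC (0.13) passed in camera with the filter on dim genes (0.13), without trend (0.13) and for genes at least 8-fold apart (0.22), and ran from 0.11 to 0.16 when samples were left out. With an estimated correlation they did not pass (adjusted p = 0.326, and 0.354 without clone A1). The MDEC count of 943 became 2643 at 2-fold, 432 at 8-fold and 4591 with a limma fit. At 1.5-fold, 729 genes lay away from the other arrays in parental cells, 3183 in A1, 356 in A2, 531 in A3, 461 in A4 and 281 in A5. The difference in correlation with MDEC ran from −0.00138 to 0.00067 when samples were left out, above 0 in 3 of the 6 fits, and too few arrays remained there for a test to pass. The camera direction of the melanocyte list turned with quantile normalization (mean 0.00611, still positive) and, with its mean, under array weights (−0.0290). When samples were left out, the sign of Tfap2a (−0.0623 to 0.116) and the camera direction of these lists turned in at least 1 fit, with the range of their means: melanocyte (−0.20 to 0.24), neural crest-like (−0.0375 to 0.0538), AP-2 (−0.0662 to 0.0255), epithelial-mesenchymal (0.0650 to 0.235, positive throughout), cell cycle (−0.0770 to 3.10), interferon (−0.69 to 0.47), stress (−0.87 to 0.20) and keratinocyte genes (−0.0191 to 0.122). The mean alone changed sign for tumour-initiating cell markers (−0.0402 to 0.0515, and −0.0721 with the filter on dim genes), fibroblast and mural markers (−0.00244 to 0.256) and the genes higher in MDEC (lowest −0.00167). Where fewer samples or genes do not show it, the cause was not tested. Of the other values for single genes and lists, 492 kept their test direction and side, 34 came to pass and 19 no longer passed. Robust eBayes was not run for lists, since camera has no such option. The set of all probe sets includes controls. No paired analysis was possible because the labels pair no samples. Signal over background was not known.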

Other observations

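The PECAM1+ clones also differed from each other. The genes below were chosen after their values were seen and are given as the log2 difference from the mean of the other 5 B16F10 arrays, and some were shared between clones. Clone A3 was high in Ankrd1 (2.89), Thbs1 (2.84), Igfbp7 (2.30), Lcn2 (2.28), Timp4 (2.05), Casp12 (1.98) and Fn1 (1.72). Clone A4 was high in Timp4 (3.15), Scrg1 (3.13), Cda (2.60), Bcan (2.22) and Fabp7 (1.59). Clone A5 was high in Thbs1 (1.91), Casp12 (1.76) and Ankrd1 (1.26) and low in Arhgdib (−2.25). Clone A2 was low in Id3 (−1.65) and Uchl1 (−1.45). Clone A1 was high in Kcnj13 (4.31), the neuropeptide gene Adcyap1 (4.11), Gsta4 (3.61), the heparanase gene Hpse (3.25) and Nupr1 (2.95). Melanocyte genes lay at a median of −0.27 in clone A3 and 0.30 in clone A4.

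All tests in this part were chosen after the results were seen, except that over splits of the arrays, which was chosen before the data were examined. The 51 small nucleolar RNA genes had a median difference of −0.41 between PECAM1+ and PECAM1− samples, with 41 lower and 0 called by limma. The parental array stood apart in this, at 0.41 above the other B16F10 arrays, with clone A1 at 0.12 and the PECAM1+ clones between −0.22 and −0.06. Of the 65 genes at least 2-fold lower with separate groups, 10 lie on the chromosome of Tek (Fisher's exact p = 0.00411), 7 on that of Vegfd (0.0103) and 6 on that of Vegfb (0.0229), none of which passed Benjamini-Hochberg over 20 chromosomes.

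Cell cycle genes lay at a median of −3.15 in clone A1. A dim array would move lists matched on expression alike, but the lowest of 10000 random lists was −0.49, which excludes it. Other cells in the sample, as the main cause, would lower melanocyte genes about as much. Their median was 0.0333, with a 95% bootstrap interval over genes of −0.24 to 0.23. That excludes other cells as the main cause, but not a small share of them. A resting or stressed culture and a lasting property of the clone stay open, because 1 clone A1 sample cannot separate them.

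Genes of whole chromosomes were lower in the PECAM1+ clones than in parental cells, most on the chromosome of Vegfb (median −0.21, 95% bootstrap interval −0.24 to −0.17). The interval came from redrawing the genes of that chromosome, so it does not measure the spread between samples. Each comparison here rests on 1 PECAM1− array. Permutation of single genes among chromosomes gave p = 0.0001, the smallest it can give. It treats genes as independent, but neighbouring genes moved together in this difference (Spearman's rho = 0.21). Chance is thus excluded only for genes that vary independently, not for shifts shared by neighbours. A trend with expression level is excluded by a median of −0.21 after a loess fit. The parental array alone is excluded by a median of −0.14 against clone A1 on the chromosome of Vegfb. On that of Tek it is excluded by −0.13 (−0.14 from parental cells), while on that of Pecam1 (−0.12 and −0.07) it stays open. A chromosome number change shared by the 4 clones would lower genes along the chromosome of Vegfb in every clone against each PECAM1− sample. Its genes were split in order into 2 equal parts, and the 16 medians ran from −0.28 to −0.0697. That chromosome was chosen as the lowest against parental cells, so the medians against parental cells are no separate support. Those against clone A1 rest on the same 4 clones. The shift was uneven, with a median of −0.27 against parental cells for the first part of its genes and −0.13 for the second part. Whether all or part of the chromosome, or neither, changed in number stays open without DNA.

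Interferon genes lay at a median of −0.57 in parental cells against the other 5 B16F10 arrays, among which clone A1 was high (0.84). The PECAM1+ clones alone lay above parental cells by a smaller median of 0.36. A dim array is excluded for the −0.57, since the lowest of 10000 matched random lists was −0.26. No random lists were drawn for the 0.36. The state of the parental culture and a difference between a population and clones stay open with 1 parental sample. Over the 15 splits of the 6 arrays into 4 and 2, 1 split, the real one, gave as many as 2 called genes. The highest other gave 0. Pecam1, whose status defines the real split, was 1 of the 2, so only Cav1 bears on this question. The splits are also too few to judge.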
